A study of Mus musculus with 13 samples.

How the data were processed

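RNA of small intestinal epithelium and of intestinal adenomas from Apc mutant mice crossed with FP transgenic mice was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The sources used here do not spell out FP, so the groups are called FP-high and FP-low as in the labels. There were 13 arrays in 3 groups: 4 of normal epithelium with high FP expression, 6 of normal epithelium with low FP expression and 3 of adenomas. Per the labels' protocols, crypts were picked with glass capillaries of 40 µm diameter, RNA was extracted from each isolated crypt with a kit for very small samples, cDNA was made with the NuGEN Ovation One-Direct amplification system and it was labelled with the NuGEN Encore Biotin module. Amplification from so little RNA can drop or distort transcripts, and the number of arrays limits the precision of every value given here. The labels do not say which arrays share an animal, so all p-values measure the spread between these samples, which may in part be technical.

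The deposited values are log2 levels of 35556 probe sets per array, which the authors made with Affymetrix software: the Command Console, as the design text names it, and the Expression and Transcriptome Analysis Consoles, as the submitters' processing notes name them. The versions of these programs, the background correction, the normalization and the summarisation method are not given in the sources used here. The log2 scale was read from the range of the deposited values. Array means lay close together, while the spread within arrays did not, as described in the results. No column of per-sample values was left out.

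Probe sets were named through the platform annotation supplied with the table, with symbols checked by Entrez identifier against RefSeq genes of GRCm38.p6. Of the rows, 23410 had at least 1 gene symbol and were tested, and 12146 had none and were left out of the main tests. Exactly 1 symbol was given for 21789 probe sets, of which 21698 matched the reference by identifier and 0 needed a newer symbol. Several symbols were given for 1621 probe sets, which were counted but never named. The 1-symbol probe sets covered 19938 genes, 999 of them with more than 1 probe set. Among the tested rows 388 held values identical to another tested row. No coordinates are printed, because the deposited table names no genome build.

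Before the data were examined, 4 comparisons of group means, the rules for naming genes and 38 gene lists were fixed. The comparisons were FP-high against FP-low normal epithelium, adenoma against the average of the FP-high and FP-low means, and adenoma against each normal group alone. Each was fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values of all 13 arrays, with 1 estimate of the spread per probe set shared by the 3 groups. The groups share replicate numbers in the labels, so it was checked whether arrays of the same number deviate together from their group means. FP-high and adenoma arrays did, with correlations of 0.233, 0.103 and 0.220 for numbers 1, 2 and 3, all over the bound of 0.1, so that the fit with the replicate number as a block is given beside the results of that comparison. Pairs with FP-low arrays ran from -0.361 to 0.178, and among them only FP-high with FP-low replicate 2 passed the bound. FP-high replicate 2 correlated better with an adenoma array of another number (0.204) than with that of its own. Any pairing is read from this check and not from the labels. FP-high replicates 1, 2 and 3 were low in Xist, an RNA of female cells (log2 levels 2.65 to 3.61). Adenoma replicates 1, 2 and 3 were high in it (8.88 to 9.71), which argues against 1 animal behind each of these pairs. What makes their deviations correlate was not tested. No filter on level, no further normalization and no covariate entered the main model. P-values were adjusted by Benjamini and Hochberg over the 23410 probe sets, and an adjusted p under 0.05 counted as a call. Fold changes are differences of mean log2 level, given with the standard error from limma. Level SDs are between arrays of a group.

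The lists covered pathways and markers of the cell types a crypt or adenoma sample could hold. Each list gene was read on its brightest probe set with 1 symbol, and the 37 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. Exact two-sided permutation of array labels on the mean of each list per array was added after the data had been seen. Members past the threshold were counted over all probe sets tested and, separately, adjusted over the list alone.

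Genes were named by rule. For FP-high against FP-low and for adenoma against normal these were the 8 higher and 8 lower genes with the largest fold change among called probe sets with 1 symbol whose groups did not overlap. Where fewer than 4 qualified in a direction, the 8 with the smallest p were taken, and those that did not pass are described as such. For the comparisons with 1 normal group the first 3 each way were taken. Up to 4 members of each list discussed, those with the smallest adjusted p, and Apc were named as well. Predicted genes, small RNAs, immunoglobulin and T cell receptor segments and olfactory or vomeronasal receptors were counted and not named. Xist and the Y-linked transcripts come from a list fixed in advance and are shown per array.

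The steps were tested on simulated data with a known set of changed probe sets. For adenoma against normal epithelium, the fit over 23410 probe sets recovered 53.7% of changes of 1 log2 unit, 83.6% of changes of 2 and 98.5% of changes of 4, with 1 false call. For FP-high against FP-low the shares were 50.8%, 79.1% and 100%, with 37 false calls.

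Alternatives fixed in advance were quantile normalization, centring on array medians, filters on level, every row of the table, 1-symbol probe sets only, a trended and robust variance, array weights, a fit of only the groups compared, the replicate number as a block, other thresholds and leaving out each array in turn. The block was fitted on the 11 arrays whose number occurs in more than 1 group, FP-low arrays included. It thus left out FP-low replicates 5 and 6. Chosen after the data had been seen were the joint reading of all results without FP-high replicate 1, a covariate for arrays with high Xist, both together, and 1 row kept per set of identical rows. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.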

Results

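Gene expression was measured in normal epithelium of the mouse small intestine and in adenomas of Apc mutant mice that also carried FP transgenes. Loss of Apc, a negative regulator of Wnt signalling, starts adenomas in this model. Normal epithelium lay next to adenomas and was divided by the submitters into FP-high samples (n = 4) and FP-low samples (n = 6). Adenomas made up the remaining group (n = 3). The title of the series places the work in the search for expression signatures that come before intestinal tumours, and the comparison of FP-high with FP-low normal epithelium addresses that question.

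The array labelled FP-high replicate 1 stood apart from the other 12. Its log2 values had an SD of 1.21 over the tested probe sets, against 1.89 to 2.10 in the others. Its median correlation with the other arrays was 0.762, whereas pairs among the other 12 arrays correlated at 0.920 to 0.985. Regressed on the mean of the other normal arrays, its deviation had a slope of -0.52 per log2 unit, so bright probe sets read lower and dim ones higher. Slopes of the other arrays ran from -0.02 to 0.12. Only 362 of its probe sets exceeded a log2 level of 9, against 1091 to 1320 in each of the others. Called lists are therefore given with and without this array.

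**Figure D1:**
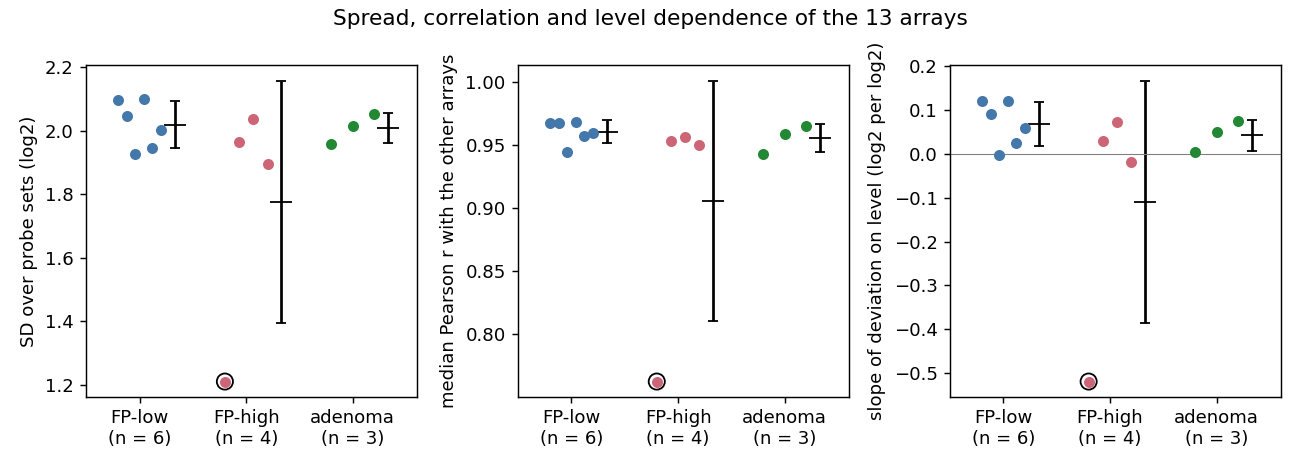
Per array, the SD of log2 values over 23410 probe sets (left), the median Pearson correlation with the other 12 arrays (middle) and the slope of its deviation on the mean level of the normal arrays (right), for FP-low (n = 6), FP-high (n = 4) and adenoma samples (n = 3). Points are arrays, bars are group means ± SD, and the ringed point is FP-high replicate 1, at 1.21, 0.762 and -0.52.

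Sex-linked transcripts did not divide evenly between the groups. Xist, the RNA that silences 1 X chromosome in female cells, was at a log2 level of 8.88 to 9.71 in all 3 adenoma arrays. In the normal arrays it was at 8.64 in FP-high replicate 4, 8.74 in FP-low replicate 6 and 3.61 or lower in the other 8. The Y-linked gene Eif2s3y ran the opposite way, at 2.01 to 2.25 in the 5 arrays with high Xist and at 4.43 to 6.87 in the other 8. The adenoma samples thus differed from 8 of the 10 normal samples in these transcripts too. The list of sex-linked transcripts, which holds genes moving both ways, was not called by camera between FP-high and FP-low samples (adjusted p = 0.435) or between adenomas and normal epithelium (adjusted p = 0.114).

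**Figure D2:**
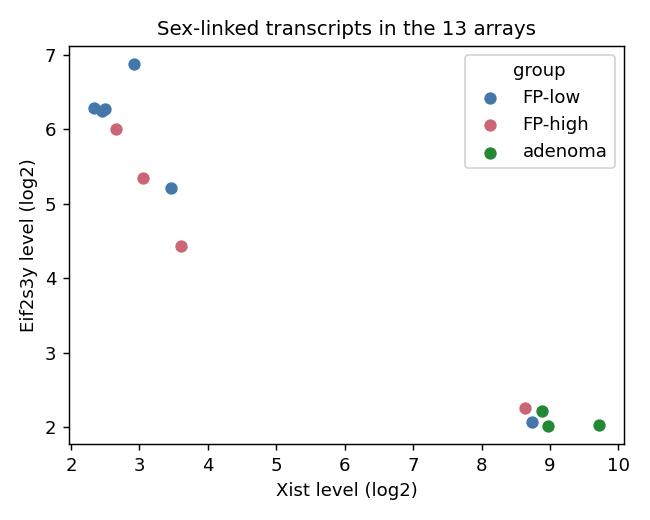
Log2 level of Xist (horizontal) against log2 level of Eif2s3y (vertical) in the 13 arrays, coloured by group. All 3 adenomas, FP-high replicate 4 and FP-low replicate 6 lie at high Xist (8.64 to 9.71) and low Eif2s3y (2.01 to 2.25).

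In FP-high normal epithelium, transcripts of dividing cells were at lower levels than in FP-low epithelium as a list, although no single gene passed the test. All 37 measured cell cycle genes had a lower mean in FP-high samples, with a median log2 difference of -0.95 (limma camera, adjusted p = 1.75e-23; adjusted p = 0.349 with an estimated correlation). Examples are Hmmr, which acts at the mitotic spindle, at -1.14 ± 0.19 (SE), Mcm4, a subunit of the replicative helicase, at -1.23 ± 0.23, Prc1, which bundles microtubules in cytokinesis, at -1.81 ± 0.36, and the mitotic kinase Plk1 at -1.05 ± 0.22. None of the 37 passed over all probe sets, and 27 did when adjusted over the list alone. Each of the 4 FP-high arrays had a list mean (-1.66, -0.60, -0.41 and -1.15 relative to the FP-low mean) below all 6 FP-low arrays (-0.26 to 0.13). The exact permutation test of these means gave p = 0.0048, the smallest that 210 splits can give when two-sided, or 0.088 adjusted over 37 lists. With fry, which asks whether the genes of a list move on balance in 1 direction, the adjusted p was 0.035. Without FP-high replicate 1 the median difference was -0.78, with adjusted p = 2.64e-24 by camera, adjusted p = 0.062 with an estimated correlation and 0.027 by fry.

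Lists tied to growth and to chromatin lay lower along with the cell cycle. Of 37 ribosome biogenesis genes 35 were lower in FP-high samples, with a median of -0.68 (camera, adjusted p = 1.25e-13; adjusted p = 0.349 with an estimated correlation). The rRNA-processing factor Wdr75 stood at -1.52 ± 0.25 and Heatr1 at -1.19 ± 0.31, and 12 members passed when adjusted over the list alone. The median of this list was -0.37 without FP-high replicate 1 (adjusted p = 5.99e-11, and 0.142 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.67 (28 of 29 lower; adjusted p = 1.01e-09, and 0.691 with an estimated correlation), which shrank to -0.18 without FP-high replicate 1 (adjusted p = 6.13e-05, and 0.382 with an estimated correlation). The list for DNA methylation and chromatin silencing had a median of -0.52 with 27 of 30 members lower (adjusted p = 6.25e-08, and 0.349 with an estimated correlation). Its examples are the histone methyltransferase Setdb1 at -0.76 ± 0.14, the chromatin remodeller Hells at -1.41 ± 0.34 and Uhrf1, which recruits the maintenance DNA methyltransferase, at -1.33 ± 0.39. Without FP-high replicate 1 its median was -0.25, with adjusted p = 7.05e-07 by camera and 0.042 with an estimated correlation. Intestinal stem cell genes had a median of -0.48 (18 of 19 lower; adjusted p = 7.53e-06, and 0.349 with an estimated correlation), Lrig1 and Hopx being at -0.75 ± 0.25 and -0.81 ± 0.32. Their median was -0.40 without FP-high replicate 1 (adjusted p = 0.00025, and 0.237 with an estimated correlation). Immediate early and heat shock genes had a median of -0.24 (24 of 29 lower; adjusted p = 0.00073, and 0.357 with an estimated correlation), with Dusp1 at -1.41 ± 0.34. The median of the immediate early list was -0.23 without FP-high replicate 1 (adjusted p = 0.0012, and 0.382 with an estimated correlation).

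Enterocyte genes lay higher in FP-high samples, with 32 of 33 members above the FP-low mean and a median of 0.69 (camera, adjusted p = 0.0044; adjusted p = 0.722 with an estimated correlation). Fabp1, the liver-type fatty acid binding protein of absorptive cells, was at 1.09 ± 0.50, lactase (Lct) at 1.32 ± 0.63 and adenosine deaminase (Ada) at 1.51 ± 0.61, none of them past the threshold. The list means of the 4 FP-high arrays were -1.32, 1.43, 2.23 and 0.29 and those of FP-low arrays ran from -1.04 to 0.92, so the groups overlapped. Without FP-high replicate 1 the median was 1.33 (adjusted p = 1.33e-16, and 0.320 with an estimated correlation), and without FP-high replicate 3 it was 0.11 (adjusted p = 0.784). The call also ended without FP-high replicate 2 (adjusted p = 0.203), FP-low replicate 3 (adjusted p = 0.061) or FP-low replicate 6 (adjusted p = 0.060). T cell and intraepithelial lymphocyte markers had a median of 0.30 (22 of 23 higher; adjusted p = 0.0052, and 0.619 with an estimated correlation), with the cytotoxic granule gene Nkg7 at 1.06 ± 0.30 and Cd8a at 0.74 ± 0.34. Their median was 0.20 without FP-high replicate 1 (adjusted p = 0.0029, and 0.382 with an estimated correlation), and without FP-high replicate 3 the call ended (adjusted p = 0.133). Macrophage and neutrophil markers were at the threshold (median 0.19, adjusted p = 0.05, and 0.691 with an estimated correlation), and their call ended without any of FP-high replicates 1, 2 and 3 (medians 0.12, 0.13 and 0.23, adjusted p = 0.115, 0.068 and 0.127), FP-low replicates 1, 2, 4 and 6 (adjusted p = 0.056 to 0.066) or adenoma replicate 2 (adjusted p = 0.056). After quantile normalization the median of that list was -0.0049 (adjusted p = 0.809).

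Calls for 4 further lists ended when FP-high replicate 1 was left out. Mitochondrial respiration had a median of -0.58 with it (adjusted p = 5.66e-07, and 0.713 with an estimated correlation) and 0.02 without it (adjusted p = 0.962), and its median was also above 0 after quantile normalization, at 0.05 (adjusted p = 0.890). The Paneth cell list, with the antimicrobial gene Lyz1 at -1.34 ± 0.74, went from -0.75 (adjusted p = 0.0038, and 0.691 with an estimated correlation) to -0.30 (adjusted p = 0.248). Goblet cell genes went from -0.43 (adjusted p = 0.014, and 0.713 with an estimated correlation) to -0.02 (adjusted p = 0.962). Lipid and sterol genes had a median of -0.21 with it (adjusted p = 0.022, and 0.713 with an estimated correlation) and 0.0026 without it (adjusted p = 0.569), and their call also ended without FP-low replicate 1 (adjusted p = 0.108) or 4 (adjusted p = 0.065). In all, camera called 13 of 37 lists with all arrays and 12 without FP-high replicate 1, of which 8 were shared. With all arrays fry called the cell cycle list alone.

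**Figure D3:**
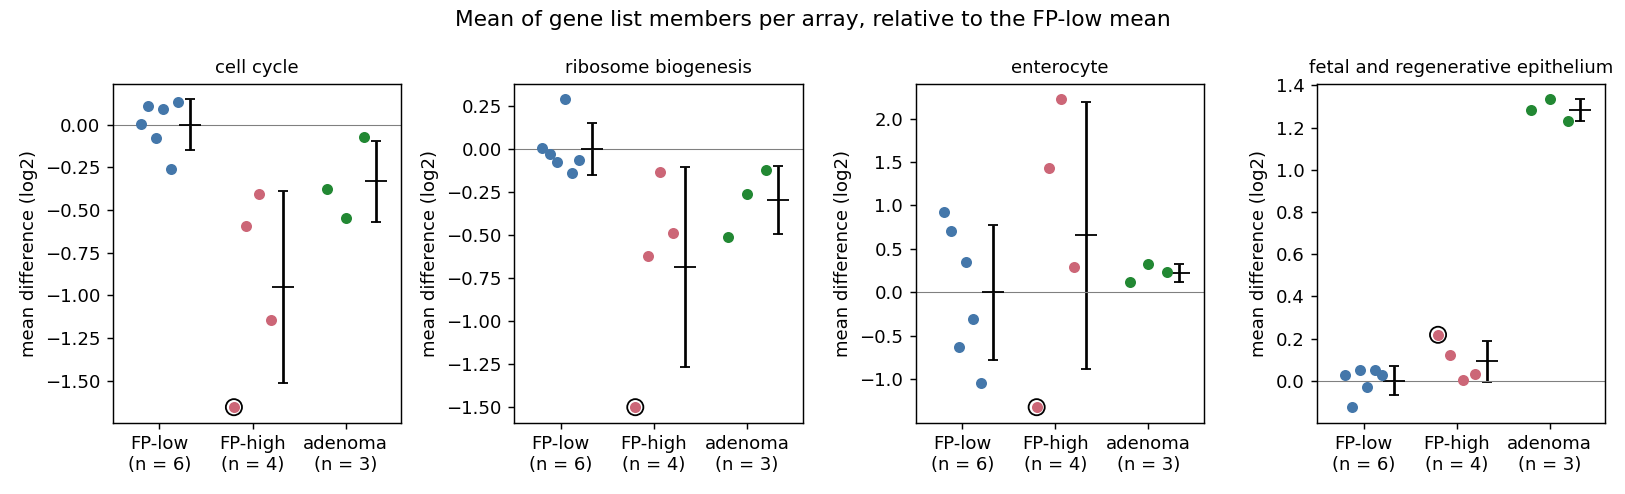
Mean log2 difference of list members from the FP-low mean, per array, for cell cycle (37 genes), ribosome biogenesis (37), enterocyte (33) and fetal and regenerative epithelium genes (18). Points are arrays, bars are group means ± SD, and the ringed point is FP-high replicate 1. All 4 FP-high arrays lie below all 6 FP-low arrays for the cell cycle, and all 3 adenomas lie at 1.23 to 1.34 for the fetal and regenerative list.

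Among single genes, limma called 0 of 23410 probe sets between FP-high and FP-low epithelium (smallest adjusted p = 0.068), while 2979 had an unadjusted p under 0.05 where chance gives 1170.5 on average, 1118 higher and 1861 lower. Probe sets vary together and the spread of that chance count was not measured, so the excess cannot be set against chance. The genes with the smallest p on the lower side included 4 with roles in mitosis. Knl1, a kinetochore scaffold, went from 7.18 ± 0.38 (SD, n = 6) to 4.82 ± 0.83 (n = 4; adjusted p = 0.081). Ncapg2, a condensin subunit, differed by -1.55 ± 0.23 (SE), Nuf2, another kinetochore protein, by -1.14 ± 0.18 and Hmmr as above. The others were Fam111a at -2.36 ± 0.32 (adjusted p = 0.068), the TBP-like factor Tbpl1 at -1.38 ± 0.19, the palmitoyltransferase Zdhhc2 at -1.91 ± 0.27 and the chromatin protein Hmgb3 at -1.38 ± 0.23. On the higher side the smallest p belonged to Zc3h6 (0.82 ± 0.16, adjusted p = 0.142), the small GTPase Rab30 (1.62 ± 0.34), H2-M10.6 (0.54 ± 0.12), Cyria (0.87 ± 0.20), the histamine receptor Hrh4 (0.58 ± 0.14), the synaptic scaffold Shank1 (0.42 ± 0.11), Cyp3a57 (0.54 ± 0.14) and Tmed8 (0.57 ± 0.14). These higher-side genes were dim in FP-low samples, with mean log2 levels from 2.27 (H2-M10.6) to 4.44 (Tmed8). Medians of the FP-low arrays were 4.57 to 4.62. FP-high replicate 1, in which dim probe sets read higher, is among the FP-high arrays, and its share in these differences was not tested. Apc itself differed by -0.06 ± 0.19 (adjusted p = 0.861). The count depended on single arrays: it was 136 (6 higher, 130 lower) without FP-high replicate 3, 12 without FP-high replicate 2, 6 without FP-high replicate 4, 1 without FP-low replicate 3 and 1 without FP-low replicate 6, and it stayed at 0 without FP-high replicate 1.

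Most genes called between adenomas and normal epithelium were at higher levels in adenomas. Limma called 213 probe sets, 207 higher and 6 lower, which covered 186 genes, while array weights gave 692 higher and 461 lower, and a block for the replicate number gave 66 higher and 1 lower. Wfdc18, a secreted whey acidic protein family member, rose from 4.01 ± 0.19 in FP-low (SD, n = 6) and 4.20 ± 0.22 in FP-high samples (n = 4) to 10.94 ± 0.69 in adenomas (n = 3), a log2 fold change of 6.83 ± 0.23 (SE, adjusted p = 8.73e-09). Fabp6, the ileal bile acid binding protein, rose by 6.39 ± 0.85, the amino acid transporter Slc38a4 by 5.73 ± 0.40 and Sptssb, a subunit of serine palmitoyltransferase, by 5.56 ± 0.44. Ifitm1, an interferon-induced membrane protein, rose by 5.12 ± 0.34, and the calcium or phospholipid binding proteins S100a6, Anxa10 and Anxa1 rose by 4.87 ± 0.63, 4.72 ± 0.39 and 4.51 ± 0.23. In each of these 8 genes all 3 adenomas lay above all 10 normal arrays, as the rule for naming them required. Over all tested probe sets 929, or 3.97%, had adenoma arrays all above or all below the normal ones, against 0.699% by chance. On the lower side 4 genes qualified: the transcription factor Fosb fell by 1.65 on the log2 scale (adjusted p = 0.047), the carboxylesterase Ces1e by 1.30 (adjusted p = 0.029), the TGF-beta family ligand Gdf11 by 0.79 (adjusted p = 0.049) and the xylosyltransferase Xxylt1 by 0.75 (adjusted p = 0.042). Each of these 4 calls ended when any 1 adenoma array was left out, with adjusted p between 0.111 and 0.315. Without 1 normal array, Ces1e lost its call for FP-high replicate 4 (adjusted p = 0.053) and FP-low replicate 1 (adjusted p = 0.052), and Fosb, Gdf11 and Xxylt1 lost theirs for 7 or 8 of the 10 normal arrays (adjusted p = 0.058 to 0.083). Apc was at 0.27 ± 0.19 (adjusted p = 0.606).

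**Figure D4:**
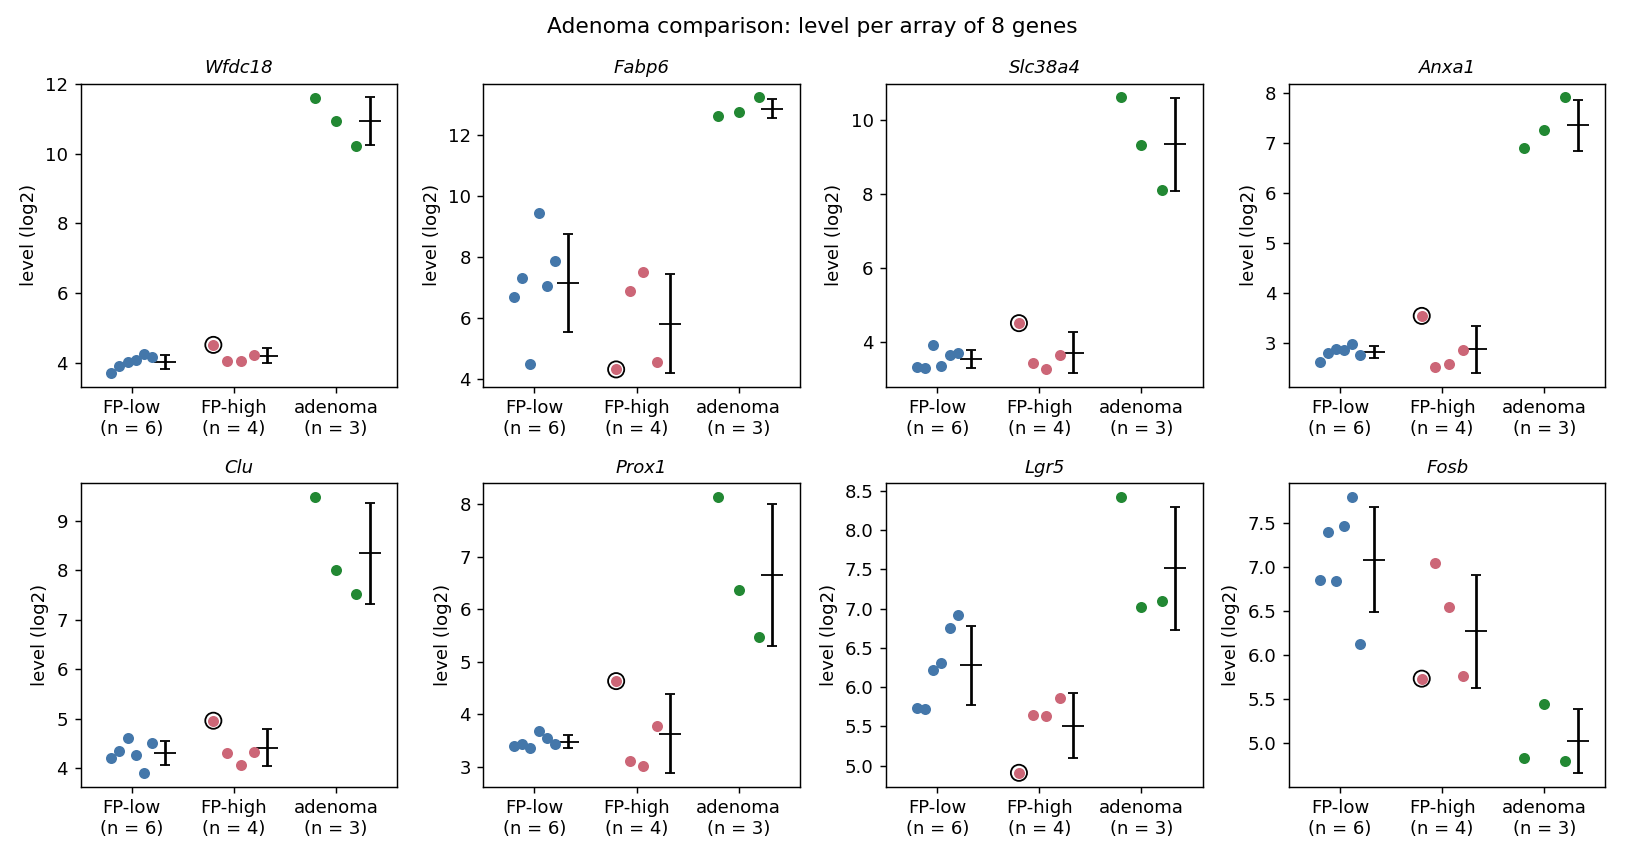
Log2 level per array of 8 genes in FP-low (n = 6), FP-high (n = 4) and adenoma samples (n = 3). Points are arrays, bars are group means ± SD, and the ringed point is FP-high replicate 1. Wfdc18 has means of 4.01, 4.20 and 10.94, and Fosb, lower in adenomas, has 7.08, 6.27 and 5.03.

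The fetal and regenerative epithelium list had the clearest shift in adenomas. Of its 18 measured members none was called as lower over all probe sets and 7 were called as higher, among them Anxa1, the chaperone clusterin (Clu, 3.98 ± 0.32), the alarmin Il33 (2.70 ± 0.23) and Anxa3 (2.88 ± 0.26). By sign 9 members were higher and 9 lower, with a median of 0.24 and a mean of 1.24. Camera gave adjusted p = 1.05e-07, or adjusted p = 0.044 with an estimated correlation, and fry gave 2.59e-05. The median was 0.32 without FP-high replicate 1 (adjusted p = 1.21e-08, and 0.0055 with an estimated correlation). When adjusted over the list alone, 8 members passed as higher and 1 as lower.

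Targets of Wnt and beta-catenin signalling rose in adenomas as a list (median 0.20, 21 of 30 higher; camera, adjusted p = 0.000105; adjusted p = 0.363 with an estimated correlation), with a median of 0.17 without FP-high replicate 1 (adjusted p = 0.00052, and 0.555 with an estimated correlation). The list did not pass with fry (adjusted p = 0.149). The 4 called members, the same number as when adjusted over the list alone, were the transcription factor Prox1 (3.11 ± 0.44), the feedback inhibitor Nkd1 (2.08 ± 0.38), the hyaluronan receptor Cd44 (1.94 ± 0.35) and the stem cell receptor Lgr5 (1.62 ± 0.33). Prox1 stayed called without any 1 array, whereas Cd44, Nkd1 and Lgr5 lost their calls when adenoma replicate 1 was left out, at adjusted p = 0.111, 0.077 and 0.298. Leaving out adenoma replicate 2 also ended them, at 0.076, 0.132 and 0.083, and leaving out adenoma replicate 3 ended Cd44 (0.088) and Lgr5 (0.068). Lgr5 further lost its call without FP-high replicate 2, 3 or 4 or FP-low replicate 1, 2, 3 or 4 (adjusted p = 0.053 to 0.071). Lgr5 was also a member of the intestinal stem cell list, which was not called (adjusted p = 0.184). Olfm4, another stem cell marker, was at -2.69 ± 0.84 (adjusted p = 0.227).

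Distal small intestine genes passed as a list (median 0.61, 9 of 13 higher; camera, adjusted p = 0.0047; adjusted p = 0.363 with an estimated correlation; fry, 0.018). The 2 called members were Fabp6 and the ileal bile acid transporter Slc10a2, which rose by 3.19 ± 0.17 (adjusted p = 2.94e-07). The distal list had a median of 0.39 without FP-high replicate 1 (adjusted p = 0.0066, and 0.428 with an estimated correlation). Hypoxia and glycolysis genes passed by camera (median 0.37, 18 of 21 higher; adjusted p = 0.000105, and 0.622 with an estimated correlation), with 0 members called over all probe sets and 3 when adjusted over the list alone. Egln3, an oxygen sensor, was at 2.77 ± 0.60 (adjusted p = 0.052) and the glucose transporter Slc2a1 at 0.93 ± 0.22 (adjusted p = 0.080). Without FP-high replicate 1 the median of that list was 0.08 (adjusted p = 0.0066, and 0.566 with an estimated correlation). The BMP and TGF-beta list (median 0.17, adjusted p = 0.0080, and 0.363 with an estimated correlation) held 1 called member, the Smad corepressor Skil at 1.21 ± 0.26. The senescence list (median 0.24, adjusted p = 0.012, and 0.363 with an estimated correlation) also held 1, Igfbp7 at 0.91 ± 0.18. These lists had medians of 0.16 and 0.29 without FP-high replicate 1 (adjusted p = 0.012 and 0.0020, and 0.555 and 0.428 with an estimated correlation). The senescence call ended with the replicate number as a block (adjusted p = 0.055). Both list calls ended without adenoma replicate 1, each with adjusted p = 0.091, and so did the calls of Skil (adjusted p = 0.295) and Igfbp7 (adjusted p = 0.280), each of which also ended without several other arrays (adjusted p from 0.053). Exact permutation of array labels called 3 of the 37 lists, the fetal, Wnt and distal ones, each with p = 0.0035, the smallest that 286 splits can give, and adjusted p = 0.043.

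Markers of other cell types showed single called members in adenomas without a call for their lists. The mast cell protease Mcpt2 rose by 3.77 ± 0.30, while the mast cell list gave adjusted p = 0.550 (4 of 12 higher). In the fibroblast and matrix list (adjusted p = 0.184) decorin (Dcn) rose by 2.36 ± 0.45, Sparc by 1.30 ± 0.24 and fibronectin (Fn1) by 1.22 ± 0.22. Endothelial Ecscr rose by 1.34 ± 0.24, the leukocyte antigen Ptprc by 0.79 ± 0.16 and the smooth muscle tropomyosin Tpm2 by 0.99 ± 0.17, in lists with adjusted p = 0.528, 0.237 and 0.394. Of these 7 genes Mcpt2 alone stayed called without any 1 array, and all the others lost their calls without adenoma replicate 1, at adjusted p between 0.0995 and 0.301. Among these, Fn1 lost it in no other case, Ecscr also without adenoma replicate 2 (0.110), Sparc without adenoma replicate 3 (0.056), Tpm2 without adenoma replicate 2 (0.052) or 3 (0.082), Dcn without adenoma replicate 2 (0.156) or FP-low replicate 2 or 4 (0.051 each), and Ptprc without 8 other arrays (0.062 to 0.147). The cell cycle list, lower in FP-high than in FP-low epithelium, was not called between adenomas and the average of the normal groups (median 0.05, adjusted p = 0.074). Relative to the FP-low mean, its list means were -0.38, -0.54 and -0.07 in the adenoma arrays. They were -0.26 to 0.13 in FP-low and -1.66 to -0.41 in FP-high arrays.

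The number of adenoma calls moved with several single arrays and with the sex-linked difference. It was 488 (344 higher, 144 lower) without FP-high replicate 1, with all 213 calls among them, 99 without adenoma replicate 1 and 92 without adenoma replicate 2. With high Xist as a covariate, an alternative chosen after the data were seen, 28 calls were left. The median log2 fold change of the 213 probe sets was then 1.65 in the called direction, against a median size of 1.66 in the main model, and their median standard error went from 0.27 to 0.38. Fabp6 (adjusted p = 0.083), S100a6 (0.111) and Prox1 (0.128) lost their calls with this covariate at fold changes of 6.66, 4.48 and 3.06. Of the 186 calls that ended, 110 had a smaller fold change than in the main model, among them Fosb at -0.92, Ecscr at 0.78, Lgr5 at 1.12, Igfbp7 at 0.62 and Xxylt1 at -0.50. Others were larger, such as Skil at 1.61 and Dcn at 2.46. Wfdc18, Slc38a4, Sptssb, Ifitm1, Anxa10, Anxa1, Clu, Il33, Anxa3, Slc10a2 and Mcpt2 kept theirs. With the replicate number as a block 67 probe sets were called, and these 11 genes, Prox1, Cd44 and Ecscr kept their calls. That fit left out FP-low replicates 5 and 6, whose numbers no other group has, so fewer arrays may account for part of the loss. All other called genes named here for adenomas against normal epithelium lost theirs in that fit, among them S100a6 (adjusted p = 0.055), Fosb (0.056), Fabp6 (0.068), Ces1e (0.088), Lgr5 (0.118), Xxylt1 (0.138), Nkd1 (0.169) and Gdf11 (0.384). Quantile normalization ended the calls of Xxylt1 (adjusted p = 0.075), Lgr5 (0.093), Ecscr (0.149), Skil (0.264) and Igfbp7 (just above the threshold), median centring that of Fosb (0.051), and a trended and robust variance those of Fosb (0.0502) and Skil (0.060).

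The choice of normal reference was examined by setting adenomas against each normal group. Against FP-low epithelium limma called 129 probe sets, 125 higher and 4 lower. Wfdc18 rose by 6.92 ± 0.25, Slc38a4 by 5.82 ± 0.43 and Fabp6 by 5.72 ± 0.91, while Ces1e fell by 1.63, Fosb by 2.05 and the zinc finger gene Zc3h4 by 0.87. Against FP-high epithelium 179 were called, 175 higher and 4 lower. Fabp6 rose by 7.05 ± 0.99, Wfdc18 by 6.74 ± 0.27 and Slc38a4 by 5.65 ± 0.46, while Xxylt1 fell by 0.93 and Lrrc15 by 0.79, and Zc3h6 at -0.88 ± 0.19 did not pass (adjusted p = 0.052). FP-high and adenoma arrays of the same number deviated together, although the arrays of each such pair differed in Xist level. With the replicate number as a block 51 probe sets were called against FP-high epithelium. Wfdc18 and Slc38a4 kept their calls in that fit, while Fabp6 (7.25, adjusted p = 0.086), Xxylt1 (adjusted p = 0.119) and Lrrc15 (adjusted p = 0.235) did not. Against FP-low epithelium the block ended the calls of Fabp6 (adjusted p = 0.173), Ces1e (0.080), Fosb (0.052) and Zc3h4 (0.267). The Xist covariate ended these calls too (0.187, 0.149, 0.669 and 0.434). Against FP-high epithelium it ended those of Fabp6 (0.065), Xxylt1 (0.370) and Lrrc15 (0.187). Quantile normalization also ended the call of Xxylt1 against FP-high epithelium (adjusted p = 0.063), a trended and robust variance ended that of Zc3h4 against FP-low epithelium (0.057) and brought Zc3h6 under the threshold (0.047), and a fit of only the groups compared ended those of Xxylt1 (0.180) and Lrrc15 (0.350). Fabp6 against FP-low samples lost its call without any 1 adenoma array (adjusted p between 0.051 and 0.062), as did the 5 called lower genes named for these comparisons except Ces1e, whose call ended without adenoma replicate 2 (0.076) or 3 (0.061). Fosb, Zc3h4, Xxylt1 and Lrrc15 also lost their calls without some normal arrays (adjusted p from 0.050 to 0.094). The count against FP-low epithelium was 370 without FP-high replicate 1, 82 without adenoma replicate 1 and 78 without adenoma replicate 2, and that against FP-high epithelium was 281 without FP-high replicate 3, 72 without adenoma replicate 1 and 88 without adenoma replicate 2. Fits of only the groups compared gave 343 calls against FP-low and 46 against FP-high epithelium, the latter holding FP-high replicate 1. Whether the 2 normal references give different calls was not tested beyond the comparison of FP-high with FP-low epithelium.

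Changes from FP-low to FP-high epithelium were set against changes from FP-low epithelium to adenoma to ask whether they ran in 1 direction. Across 23410 probe sets, which are not independent replicates, their log2 fold changes correlated at r = 0.152, and at 0.081 when adenoma replicate 1 was left out. Unchanged groups were simulated by drawing deviations of all 13 arrays from their group means with replacement, with the simulated FP-low group shared by both changes. They gave a mean r of 0.349, with a range of -0.785 to 0.912 over 100 draws. The same array could be drawn into several groups and the spread is wide, so this simulation cannot decide whether a direction is shared. The observed covariance was 0.0304 and the simulated one 0.0319 ± 0.0482 (SD), a difference of -0.0014. Without FP-high replicate 1 the covariances were 0.0280 and 0.0268. With the 6 FP-low arrays split into 2 sets of 3, r averaged 0.040 over 20 splits (-0.124 to 0.212). Since 0 probe sets were called between FP-high and FP-low samples, none was shared with the 129 adenoma calls, and independent lists would share 0. Of the 207 probe sets higher in adenomas than in normal epithelium, 86 were higher in FP-high than in FP-low samples, with a median difference of -0.06.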

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

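The tests on leaving out FP-high replicate 1, on calls made without the Xist-high normal arrays and with the Xist covariate, and the count of splits that part same-numbered arrays, were chosen after the results were seen. The other splits, the level-matched lists, the enterocyte covariate and the first test of sex were set out before those tests were run. Except for the splits, they were framed around patterns already seen in these arrays.

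In 78 groups of 4 or 6 arrays, 12 held 1 array far from the others by Dixon's test, where chance gives about 1 in 20 groups, or 3.9. FP-high replicate 1 accounted for 4: its median correlation with the other arrays (0.762, nearest FP-high array 0.950), Hmgb3 (5.91, nearest 6.79), H2-M10.6 (3.00, nearest 2.77) and Sptssb (4.76, nearest 3.13). The others were Rab30 in FP-high replicate 2 (6.56, nearest 5.14), Cyp3a57 (2.70) and Zdhhc2 (5.32) in FP-low replicate 3, Tbpl1 (7.41) and Sptssb (4.90) in FP-low replicate 1, S100a6 in FP-low replicate 2 (4.09), Xxylt1 in FP-low replicate 6 (3.85) and the ribosome biogenesis mean in FP-low replicate 4 (0.29 above the group mean).

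Other splits of the same arrays were fitted to ask whether the counts of calls could arise from any grouping. For adenomas against FP-low epithelium, 1 of 84 splits, the real one itself, gave as many calls (343, highest other 3). Chance can thus be excluded only if the arrays are independent samples. The labels do not say which arrays share an animal, so a grouping of arrays by animal is not excluded. Against FP-high epithelium it was 1 of 35 (46, highest other 1), but same-numbered arrays of these groups deviated together, and only 8 splits part all 3 pairs. The highest other count was 1 among those 8 and also 1 among the 27 others, and 8 splits are too few for a share under 0.05. For adenomas against all normal arrays 3 of 100 splits of 286, the real one among them, gave at least its 168 calls, a share under 0.05. These splits ignored that same-numbered FP-high and adenoma arrays deviated together, so chance is not excluded here. The highest other split, adenoma replicate 1 with FP-high replicates 1 and 4, gave 684, several times the real count, which points to some structure of the samples besides the groups, and what that structure is was not tested. For FP-high against FP-low epithelium the real count was 0, so all 100 drawn splits of 210 had to give as many (highest 8), and this says nothing about chance.

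The cell cycle list was lower in FP-high epithelium by camera at its preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.349, and 0.062 without FP-high replicate 1) and by permutation (adjusted p = 0.088). The tables argue against FP-high replicate 1 as the source, since the other 3 arrays differed from FP-low by -0.72 and each lay below all 6 FP-low arrays. They also argue against a change shared by genes of like level: without that array, 0 of 10000 random lists matched on level had a median as low as -0.78, the lowest being -0.37. With the enterocyte list mean as covariate the difference did not shrink, being -0.94 ± 0.19 (SE), 1.31 times its size before. That covariate was itself 1.315 higher in FP-high samples and had a slope of 0.169 ± 0.095 (SE). It varied with the group, so the fit cannot settle whether a larger share of enterocyte RNA plays a part. Lower proliferation in FP-high crypts stays open as a hypothesis. So do cell composition, animal, position of the crypt and day of amplification, none of which the labels give.

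All 3 adenomas but only 2 of the 10 normal samples were high in Xist, so the sex of the animals could account for adenoma calls. Against the 2 Xist-high normal arrays the 213 called probe sets kept a median log2 fold change of 1.65, 0.961 of that against the other 8, although these arrays took part in the calls. For 136 probe sets called against the 8 others alone, the median was 1.99 (quartiles 1.23 and 2.76) against those 2 arrays, 0.922 of its size against the 8, and 134 kept their direction. Both ratios speak against sex as the main source of these calls taken as a set. With the Xist covariate 186 of the 213 calls ended, at a median of 0.961 times their fold change before (quartiles 0.859 and 1.07), but 38 of them moved toward 0 by more than their standard error, and for those a part played by sex stays open. A shared animal behind the adenoma samples was not tested, since the labels name none.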

How the results depend on the processing

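The Xist covariate, its combination with leaving out FP-high replicate 1, the single copy of identical rows and the permutation of list means were chosen after the data were seen, and the other settings before. For FP-high against FP-low epithelium the 0 calls became 4 after quantile normalization, 3 with array weights, 6 at an adjusted p under 0.10, 837 at an unadjusted p under 0.05 with a 2-fold change, and 0 to 136 when 1 array was left out. Adenoma calls (213, 129 against FP-low and 179 against FP-high) became 1153, 868 and 594 with array weights, which gave FP-high replicate 1 a weight of 0.0646, split into 692 higher and 461 lower, 511 and 357, and 436 and 158. They were 67, 37 and 51 with the replicate block, 28, 26 and 41 with the Xist covariate, 95, 63 and 102 with that covariate and FP-high replicate 1 left out, and 702, 602 and 1297 at an unadjusted p under 0.05 with a 2-fold change. Leaving out 1 array gave 92 to 488, 78 to 370 and 72 to 281. Keeping only probe sets above the median level gave 78 against FP-low, a fit of only the groups compared gave 343 and 46, and an adjusted p under 0.10 gave 367 against FP-high. For adenoma against all normal arrays a fit of only the groups compared is the main model, so it has no value of its own. Quantile normalization changed the split from 207 higher and 6 lower to 196 and 46, from 125 and 4 to 136 and 49, and from 175 and 4 to 157 and 25. Neither scaling moved the median of all probe sets by more than 0.05.

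Lists called between FP-high and FP-low (13) became 0 with an estimated correlation, 1 with fry, 8 after quantile normalization and 0 by permutation, and 11 to 14 without 1 array. For adenomas (6) the counts were 1, 2, 12 and 3, then 3 without the dimmest probe sets, 11 with array weights and 11 with the Xist covariate, and 6 to 11 without 1 array. The correlation of the FP and adenoma changes (0.152) became 0.115 after quantile normalization, 0.205 above the median level, 0.194 for every row, 0.312 with the Xist covariate, 0.264 with that covariate and FP-high replicate 1 left out, and 0.0806 to 0.205 without 1 array. Except for the thresholds, which move the bar itself, the cause was not tested. No called gene that is named changed sign under any setting. Among called lists, the medians of macrophage and neutrophil, mitochondrial respiration and lipid genes crossed 0 in FP-high epithelium under a setting that also ended their calls. Of 36 called genes or list members named for adenomas, 22 lost the call when some 1 array was left out, 25 with the Xist covariate and 22 with the replicate block. Deviations of same-numbered arrays correlated at over 0.1 in all 3 pairs of FP-high with adenoma arrays. In pairs with FP-low arrays they correlated at -0.361 to 0.178, the highest being FP-high with FP-low replicate 2, also over 0.1. Of all 10 pairs 3 correlated best with their own number. With the block 10 lists were called between FP-high and FP-low epithelium, and the enterocyte (median 0.31, adjusted p = 0.174), goblet cell (0.0503) and macrophage (0.071) calls ended. With array weights some named genes that had not passed in adenomas did, among them Egln3 (adjusted p = 0.0090), Slc2a1 (0.013), Olfm4 (0.024), Lyz1 (0.016) and Cd74 (0.024). Egln3 also passed without the dimmest probe sets (0.047) and with a trended and robust variance (0.033). The deposited table gives no background level per probe set, so it cannot be said which fold changes against dim normal levels are only lower bounds.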

Other observations

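The tests named in this part were chosen after the results were seen, and the lists themselves before. Without FP-high replicate 1, camera called 5 more lists in adenomas, all lower. MHC class II genes had a median of -0.70 (adjusted p = 0.0064, and 0.555 with an estimated correlation), with Cd74 at -1.42 ± 0.54 and H2-Aa at -1.48 ± 0.65 over all arrays, neither past the threshold. Mitochondrial respiration had a median of -0.45 (adjusted p = 0.00075, and 0.683 with an estimated correlation), xenobiotic and antioxidant genes -0.64 (adjusted p = 0.021, and 0.683 with an estimated correlation), cytosolic ribosomal proteins -0.24 (adjusted p = 0.022, and 0.683 with an estimated correlation) and Paneth cell genes -1.02 (adjusted p = 0.025, and 0.654 with an estimated correlation). Single called genes outside these lists included Nts, the gut peptide neurotensin (2.81 ± 0.48), and the 3 called members of the lipid and sterol list, the fatty acid desaturase Scd1 (2.30 ± 0.37), the nuclear receptor Pparg (1.28 ± 0.25) and the sterol enzyme Cyp51 (0.96 ± 0.19). All 4 lost their calls without adenoma replicate 2 (adjusted p = 0.061, 0.063, 0.102 and 0.245). Scd1 also did without adenoma replicate 1 (0.051), and Pparg without adenoma replicate 1 (0.250), adenoma replicate 3 (0.076) or any of 5 normal arrays (0.051 to 0.056). Cyp51 lost it without adenoma replicate 3 (0.128) or any of 6 normal arrays (0.053 to 0.062), and with a trended and robust variance (0.115).

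In FP-high epithelium without replicate 1, lists of absorptive function also lay higher. Xenobiotic and antioxidant genes had a median of 0.76 (adjusted p = 8.33e-06, and 0.382 with an estimated correlation), proximal small intestine genes 0.58 (adjusted p = 0.00039, and 0.237 with an estimated correlation) and retinoid metabolism genes 0.24 (adjusted p = 0.0012, and 0.062 with an estimated correlation; fry, 0.027). Distal small intestine genes were at 0.17 (adjusted p = 0.0496, and 0.382 with an estimated correlation).

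Fabp6 and Slc10a2, both tied to bile acid uptake in the ileum, rose in adenomas, which may reflect a more distal origin of those samples. The other 11 distal list members had a median log2 fold change of 0.15 with quartiles of -0.19 and 1.13, and 7 of the 11 were higher. Picked after their values were seen, Muc3 was at 1.67 ± 0.87, Nr1h4 at 0.87 ± 0.42 and Fgf15 at 0.15 ± 0.17. Proximal small intestine genes were not called (median -0.30, adjusted p = 0.184), with Adh1 at -2.82 ± 0.68 (adjusted p = 0.092, but 0.00058 after quantile normalization). These members go both ways and their spread covers both outcomes, so a distal origin and a change within the adenomas cannot be told apart here, and the labels give no position along the intestine.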
